A study of Homo sapiens with 37 samples.

How the data were processed

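RNA sequencing was analysed from sorted human CD8+, conventional CD4+ and regulatory CD4+ T cells of cohorts with and without GVHD. Per the labels' protocols, total RNA was extracted with Trizol and the GeneJet Micro kit, and libraries were made with the NEBNext Ultra II Directional kit after depletion of ribosomal RNA. Per the submitters' processing notes, the authors aligned reads with STAR 2.5.4a to GRCh38, counted them per gene with featureCounts 1.5.1 and used DESeq2 for their own comparisons. The deposited values are raw gene counts, as whole numbers. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes may share reads. The deposited table held 61 library columns, of which 37 were matched to labelled samples and used, and 24 were not used here because no label describes them.

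The table held 58395 gene identifiers, of which 58275 were found in GENCODE release 29 (GRCh38), the source of symbols, biotypes and coordinates, and 120 were not. XIST, TSIX and genes of the Y chromosome, 520 identifiers, were left out of all tests. Of 97 pairs of libraries within a group, 0 were identical, and the lowest chi-square per degree of freedom between replicates was 29.26. It came from Treg no-GVHD replicates 6 and 7 (r = 0.887 on log2 CPM), the first with 3.402 M counts (M for mega). This measure rises with depth, so its lowest value need not mark the closest pair. CD8 no-GVHD replicates 4 and 5 had r = 0.981 and a chi-square of 68.79 per degree of freedom. Counts of genes are not independent of near-identical copies, such as CD8B and CD8B2 or the heat shock genes HSPA1A and HSPA1B, and mitochondrial genes share sequence with nuclear copies.

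Each GVHD comparison was fitted on the libraries of its own subset with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with an adjusted p below 0.05 as the threshold. Standard errors are the absolute log2 fold change divided by the square root of F. Subset comparisons and differences of the GVHD effect between subsets came from one model over all 6 groups. Levels are CPM, the counts scaled to one common library total, on TMM-scaled library sizes, within each subset for the GVHD comparisons and over all libraries for the subset comparisons. The comparisons, tests, gene lists, naming rule and the other settings to be tried were fixed before the data were examined.

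The 23 fixed lists of processes and T cell states and 11 fixed lists of markers of other cells or lineages were tested with camera (limma 3.58.1), two-sided, with the correlation between genes preset at 0.01, for lists with at least 3 tested genes. They were tested again with the correlation estimated from the residuals and with fry. Scores of the marker lists, the mean of log2(CPM + 1) on total counts, and 4 library measures (total count, genes detected, mitochondrial percent and percent in the 50 most abundant genes) were compared by exact permutation tests, two-sided, with SciPy 1.17.1.

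The genes named were set by rule. For each GVHD comparison these were the 10 genes of largest fold change in each direction among those passing, with a mean of at least 1 CPM and medians that differ the same way. Where fewer than 5 passed, genes of smallest p were added up to 5 and named as not passing. To them were added a fixed panel of 15 genes and, for each list called, up to 4 members of smallest p in the direction of the call. For subset comparisons and differences between subsets up to 5 genes per direction were named, with CD4, CD8A, CD8B, FOXP3, IL2RA, CTLA4, IKZF2 and IL7R always added for the subsets. Noncoding genes, receptor segments and most HLA genes were left out of the first part.

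The other settings fixed in advance were RLE size factors, no low-count filter, a stricter filter of 1 CPM, DESeq2 1.42.0, limma-voom with sample weights, and robust dispersion. They also included 1 model over all 6 groups, each library left out in turn, pseudocounts of 0.1 and 5 CPM and an unadjusted p under 0.01 for overlaps. Chosen after seeing the data were the removal of each library's smooth trend on GC content and transcript length (splines with 5 degrees of freedom, fitted on genes above a log2 CPM of 3). So were fits without 2 Tconv libraries with over 4 percent mitochondrial counts or without 1 Treg library of 3.402 M counts (M for mega), and exact permutation tests of process list scores. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for scores and figures.

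Each fit was tested on simulated counts with 200 changed genes. Genes were drawn independently, with no trend on GC content and no other structure shared between genes. For changes of 2-fold and 4-fold, edgeR recovered 11 and 54 percent in CD8 with 4 false calls among 16905 genes, 15 and 63 percent in Tconv with 5 among 16440, and 29 and 59 percent in Treg with 3 among 15661. DESeq2 recovered 26 and 78 percent in CD8 with 32 false calls, 32 and 85 percent in Tconv with 29, and 39 and 64 percent in Treg with 28. Many changes of 2-fold would therefore have been missed at these group sizes and depths. Counts with structure shared between genes can give other recoveries and more false calls than these.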

Results

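Total RNA depleted of ribosomal RNA was sequenced from 3 sorted human T cell subsets, each from a cohort with graft-versus-host disease (GVHD) and a cohort without it. GVHD is the attack of donor immune cells on the tissues of a transplant recipient, and the series title places the study after transplantation followed by cyclophosphamide. The subsets were CD8+ T cells, conventional CD4+ T cells (Tconv) and regulatory CD4+ T cells (Treg), which restrain other T cells. The 37 libraries comprised 5 CD8 libraries with GVHD and 7 without, 6 Tconv libraries with GVHD and 6 without, and 6 Treg libraries with GVHD and 7 without. Total counts per library, in M counts (M for mega), ran from 20.8 to 40.1 in CD8 with GVHD and from 27.1 to 48.8 without. In Tconv they ran from 12.1 to 35.2 with GVHD and from 18.6 to 33.5 without. In Treg they ran from 15.5 to 32.9 with GVHD and from 3.402 to 23.7 without. The labels do not say whether libraries of a group came from separate patients, so p-values here measure the spread between these libraries.

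The genes that define the sorts followed the labels of all 37 libraries. CD8A (ENSG00000153563, chromosome 2, 86784610 to 86808396 in GRCh38), a chain of the CD8 coreceptor, averaged 2030 ± 582 CPM in CD8 libraries (SD, n = 12), 2.44 ± 1.34 CPM in Tconv (n = 12) and 7.32 ± 9.29 CPM in Treg (n = 13). CD4 (ENSG00000010610, chromosome 12, 6786858 to 6820808), the coreceptor of helper T cells, averaged 690 ± 300 CPM in Tconv, 536 ± 99.2 CPM in Treg and 2.96 ± 2.55 CPM in CD8. FOXP3 (ENSG00000049768, chromosome X, 49250436 to 49264826), the lineage transcription factor of regulatory T cells, averaged 398 ± 147 CPM in Treg, 5.52 ± 7.65 CPM in Tconv and 0.469 ± 0.230 CPM in CD8. The lowest Treg library held 210 CPM of FOXP3 and the highest Tconv library 28.8 CPM.

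**Figure D1:**
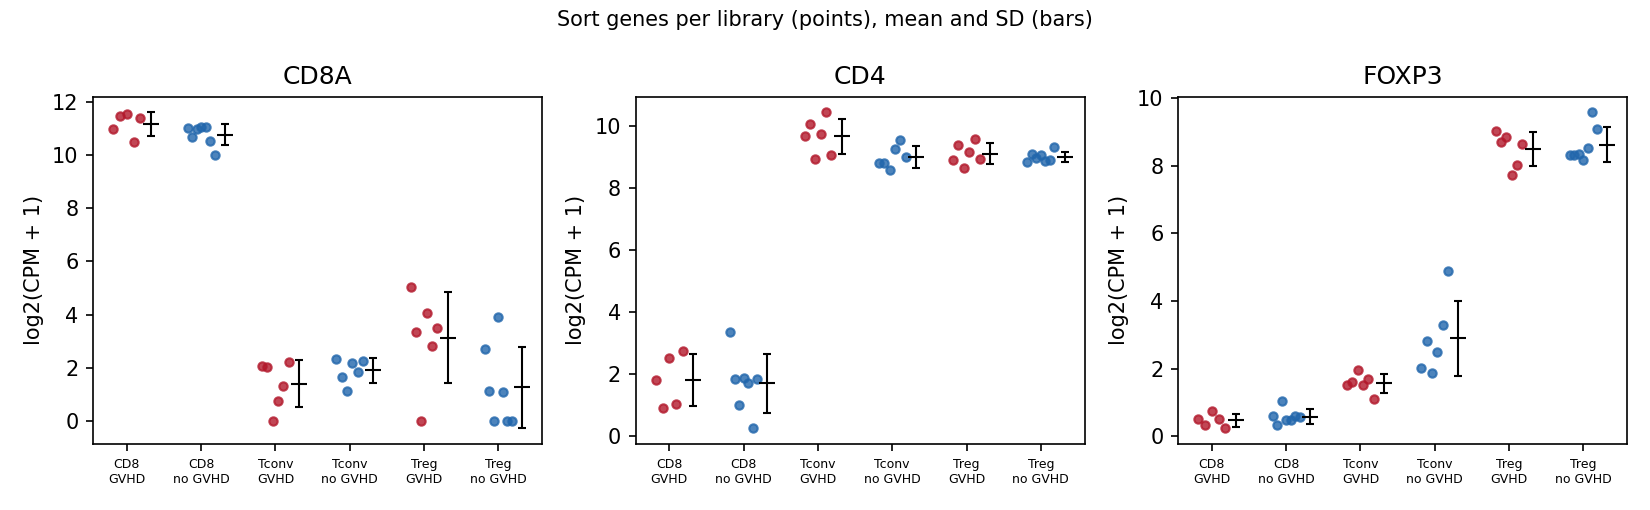
Level of CD8A, CD4 and FOXP3 in each library as log2(CPM + 1), by subset and cohort, with red points for GVHD and blue points for no GVHD, and the mean and SD as bars. CD8A separated the CD8 libraries (1027 to 2948 CPM) from Tconv (at most 4.06 CPM) and Treg (at most 32.04 CPM), and FOXP3 separated Treg from the rest.

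Between CD8 and Tconv libraries, CD8A and single genes of other functions differed. Besides CD8A (log2 fold change 9.73 ± 0.80 SE, adjusted p = 2.5e-11 by edgeR), CD8 libraries held more KLRC4, a killer lectin-like receptor gene (5.27 ± 1.81 against 0.0109 ± 0.0289 CPM), and more PDGFRB, a growth factor receptor (76.1 ± 130 against 0.182 ± 0.425 CPM). Tconv libraries held more TSHZ2, a zinc finger gene (21.8 ± 16.2 against 0.0296 ± 0.0434 CPM), more ST6GALNAC1, a sialyltransferase (24.8 ± 10.5 against 0.0749 ± 0.108 CPM), and more IL7R, the interleukin 7 receptor (969 ± 416 against 142 ± 116 CPM). CTLA4, an inhibitory receptor, did not pass between them (log2 fold change -0.25 ± 0.28 SE, adjusted p = 0.693 by edgeR). In this comparison edgeR called 1004 genes higher in CD8 and 1304 higher in Tconv of 20335 tested, and in the subset calls CD8 versus Tconv limma-voom with sample weights gave 5845 in all. CD8B2 was also called, but it is a near-identical copy of CD8B and the counts cannot tell them apart.

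Between CD8 and Treg libraries, Treg libraries held far more IL2RA, the alpha chain of the interleukin 2 receptor that marks regulatory T cells (410 ± 91.7 against 0.557 ± 0.728 CPM, log2 fold change -10.23 ± 0.62 SE for CD8 against Treg, adjusted p = 2.3e-15 by edgeR). IKZF2, which encodes the transcription factor Helios, averaged 591 ± 227 CPM in Treg and 53.3 ± 66.6 CPM in CD8 (adjusted p = 1.2e-07 by edgeR), and CTLA4 averaged 310 ± 89.8 and 79.2 ± 71.4 CPM (adjusted p = 6.8e-07 by edgeR). CD8 libraries held more CD248, a membrane glycoprotein gene (13.3 ± 11.9 against 0.0408 ± 0.147 CPM), and S100B, a calcium-binding protein gene, which had 0 counts in the Treg libraries and 3.17 ± 6.44 CPM in CD8. In this comparison edgeR called 3348 genes higher in CD8 and 3137 higher in Treg.

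Between Treg and Tconv libraries, FOXP3 (log2 fold change 6.54 ± 0.34 SE, adjusted p = 1.4e-16 by edgeR), IL2RA (5.76 ± 0.46), IKZF2 (5.68 ± 0.54) and CTLA4 (1.80 ± 0.28) were higher in Treg, and IL7R was lower (-1.99 ± 0.34, adjusted p = 6.8e-05 by edgeR). LAYN, which encodes the hyaluronan receptor layilin, averaged 36.9 ± 24.4 CPM in Treg and 0.428 ± 0.413 CPM in Tconv, and ARG1, the arginase of the urea cycle, 4.16 ± 3.13 and 0.0247 ± 0.0403 CPM. FCRL6, an Fc receptor-like gene, was higher in Tconv (27.8 ± 51.1 against 0.697 ± 1.70 CPM). MT-ATP8 was also higher in Tconv (59.6 ± 101 against 1.33 ± 0.940 CPM). It overlaps MT-ATP6 on the mitochondrial genome, so its count is uncertain. In all 1548 genes were called higher in Treg and 1657 higher in Tconv by edgeR. Monocyte markers were also higher in Treg libraries, in both cohorts. On total counts the monocyte marker LYZ averaged 231 CPM with GVHD and 456 CPM without in Treg. It averaged 17.9 and 74.6 CPM in Tconv and 27.7 and 50.8 CPM in CD8. Monocyte RNA is therefore a candidate source of some genes called higher in Treg, here and against CD8, which was not tested.

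Within CD8+ T cells the question was which genes set the GVHD cohort apart from the cohort without GVHD. At the level of fixed gene lists, cytotoxic effector genes stood higher and naive and central memory genes and type I interferon response genes stood lower in GVHD by camera with the preset correlation, while edgeR called no single gene over all genes. With an estimated correlation these calls were lost (adjusted p = 0.600, 0.578 and 0.600), and 57 of 100 splits of the libraries called as many lists. ZNF683 (ENSG00000176083, chromosome 1, 26361634 to 26374522), which encodes the tissue-residency transcription factor Hobit, averaged 138 ± 95.2 CPM with GVHD and 24.9 ± 25.3 CPM without (SD, n = 5 and 7), above the no-GVHD median in 5 of 5 GVHD libraries. TXK, a kinase of resting T cells, averaged 10.4 ± 7.24 CPM with GVHD and 71.9 ± 89.8 CPM without, below the no-GVHD median in 5 of 5. No-GVHD replicates 6 and 7 held 230 and 171 CPM of TXK, against 3.88 to 36.7 CPM in the others, and no fit left out both.

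Over the whole CD8 comparison, edgeR's quasi-likelihood test called 0 genes higher and 0 lower of 17352 tested (smallest adjusted p = 0.591), with 1457 genes at an unadjusted p under 0.05 where chance gives 868. DESeq2 called 16 genes higher and 36 lower, and limma-voom with sample weights called 203 higher and 333 lower. Taking each library's trend on GC content and transcript length out of the counts, a setting chosen after seeing the data, ended each of the 536 limma-voom calls. DESeq2 then called 3 genes higher and 39 lower, of which 5 were among its 52 before. Of the 15 fixed panel genes 0 passed when adjusted over the list alone, and 0 passed over all genes tested by edgeR. HLA-DRA, an antigen presentation gene of activated T cells, averaged 378 ± 89.9 against 214 ± 129 CPM, and ITGB7, the beta chain of the gut-homing integrin, 554 ± 135 against 334 ± 109 CPM.

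Among the genes with the smallest p in CD8, named as not passing, was SYNGR1 (ENSG00000100321, chromosome 22, 39349925 to 39385588), a synaptic vesicle protein gene. It had a log2 fold change of 3.50 ± 0.72 SE (7.998 ± 5.87 against 0.708 ± 0.626 CPM, edgeR adjusted p = 0.591). FHL3, a LIM domain protein gene, had 1.17 ± 0.28, ZNRF1, a ubiquitin ligase, 1.60 ± 0.42, VAMP5, a vesicle protein gene, 0.91 ± 0.24 and CRIP1, a cysteine-rich protein gene, 0.98 ± 0.26. On the lower side, CFAP97 (ENSG00000164323, chromosome 4, 185159665 to 185209504) had -0.84 ± 0.16 (28.9 ± 1.55 against 51.8 ± 5.06 CPM). ZNF146, a zinc finger gene, had -1.003 ± 0.22, the pseudouridine synthase gene PUS7L -0.91 ± 0.20, the kinase SLK -0.91 ± 0.20 and SMIM15 -0.72 ± 0.16, each below the no-GVHD median in 5 of 5 GVHD libraries.

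Cytotoxic effector genes, which encode granule proteins and receptors of killer lymphocytes, had a median log2 fold change of 0.56 over 18 genes in CD8, 15 of them above 0. The list was called as higher by limma's camera (adjusted p = 8.8e-05 with the preset correlation, adjusted p = 0.600 with an estimated correlation). When adjusted over the list alone 5 of its genes were higher and 0 lower, against 0 over all genes tested by edgeR. Besides ZNF683, these included FGFBP2, a secreted protein of cytotoxic cells (log2 fold change 1.08 ± 0.36 SE), and the granule protein gene NKG7 (0.76 ± 0.25). GZMB, granzyme B, had 0.54 ± 0.33 and did not pass. With the trend on GC content and transcript length taken out, the cytotoxic median was 0.10 (camera adjusted p = 0.00124) and 0 genes passed over the list alone. The naive and central memory list, which holds homing receptors and transcription factors of resting T cells, had a median of -0.54 over 17 genes, 15 of them below 0 (camera adjusted p = 0.0268, and adjusted p = 0.578 with an estimated correlation). In it 3 genes were lower and 0 higher when adjusted over the list alone, against 0 over all genes by edgeR: TXK (-2.79 ± 0.87), the myelin and lymphocyte protein gene MAL (-3.60 ± 1.18) and the costimulatory receptor CD28 (-0.94 ± 0.27). Without no-GVHD replicate 6, which held 160 CPM of MAL, MAL had -1.68. Of the list members CCR7, LEF1 and TCF7, that library held the lowest levels of the CD8 libraries (1.09, 2.78 and 34.3 CPM). Between the CD8 cohorts CCR7 (-0.54 ± 0.52) and TCF7 (-0.18 ± 0.39) did not pass. The call of the naive and central memory list was lost without GVHD replicate 1 or 4 or without no-GVHD replicate 1, 3 or 5, with adjusted p from 0.0565 to 0.191 by camera. With the trend on GC content and transcript length taken out, the median of this list was -0.43 (camera adjusted p = 0.0290). Of its genes 0 then passed over the list alone.

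Type I interferon response genes, antiviral genes induced by interferon alpha and beta, had a median log2 fold change of -0.65 in CD8, with 19 of 23 genes below 0 (camera adjusted p = 0.00276, and adjusted p = 0.600 with an estimated correlation). When adjusted over the list alone 0 of these genes were higher and 0 lower, and 0 passed over all genes by edgeR. IFI44L had -4.01 ± 1.36 SE (2.12 ± 2.10 against 34.3 ± 68.6 CPM), IFIT1 -2.34 ± 0.84 and XAF1 -1.37 ± 0.52. The interferon list was no longer called without GVHD replicate 4 (adjusted p = 0.147 by camera) or without no-GVHD replicate 7 (adjusted p = 0.0561, median -0.43), the library that held 188 CPM of IFI44L. Without that library IFI44L had -2.04 and IFIT1 -1.53. Interferon gamma response genes, which include the immunoproteasome and peptide transport, had a median of 0.40 with 15 of 18 genes above 0 (camera adjusted p = 0.00232, and adjusted p = 0.600 with an estimated correlation). In it 0 passed in either direction over the list alone or over all genes by edgeR. NLRC5, the activator of class I HLA genes, had 0.62 ± 0.20, the peptide transporter TAP1 0.84 ± 0.39 and the immunoproteasome subunit PSMB10 0.73 ± 0.33. Without GVHD replicate 2 the adjusted p of this list was 0.0532 by camera and TAP1 had 0.55.

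A further 3 lists were called in CD8 by camera, with 0 of their genes passing in either direction over the list alone or over all genes by edgeR. Oxidative phosphorylation genes had a median of 0.37 with 24 of 25 above 0 (adjusted p = 3.2e-05, and adjusted p = 0.600 with an estimated correlation), among them the respiratory chain genes COX5B (0.53 ± 0.24) and CYC1 (0.60 ± 0.28). Glycolysis genes had a median of 0.37 with 14 of 18 above 0 (adjusted p = 0.00520, and adjusted p = 0.600 with an estimated correlation), among them the glucose transporter SLC2A1 (0.49 ± 0.19) and the glycolytic enzyme gene GAPDH (0.59 ± 0.34). With the trend on GC content and transcript length taken out, the oxidative phosphorylation median was 0.13 and the glycolysis median 0.14 (camera adjusted p = 4.1e-05 and 0.00850). The regulatory T cell list had a median of -0.69 with 15 of 19 below 0 (adjusted p = 0.0328, and adjusted p = 0.600 with an estimated correlation), with IKZF2 at -2.01 ± 0.82. In all, 8 of its 20 genes also stand in other lists. That call was lost without GVHD replicate 4 or without no-GVHD replicate 1, 5 or 6, with adjusted p from 0.0627 to 0.202 by camera. Its median was -0.34 without no-GVHD replicate 6. Without GVHD replicate 4 the number of lists called in CD8 went from 7 to 4. Slopes of expression on GC content and on transcript length were compared between the cohorts of each subset, and 0 of 6 passed. In CD8 the slope of expression on GC content averaged 0.195 ± 0.217 log2 per 10 percentage points with GVHD and -0.139 ± 0.128 without (exact permutation test, two-sided, p = 0.0101, adjusted p = 0.0606 over 6 tests, above the no-GVHD median in 5 of 5). The slope on transcript length, in log2 per doubling, averaged -0.107 ± 0.107 with GVHD and 0.0763 ± 0.151 without in CD8 (exact p = 0.0505, adjusted p = 0.128, above the no-GVHD median in 0 of 5).

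**Figure D2:**
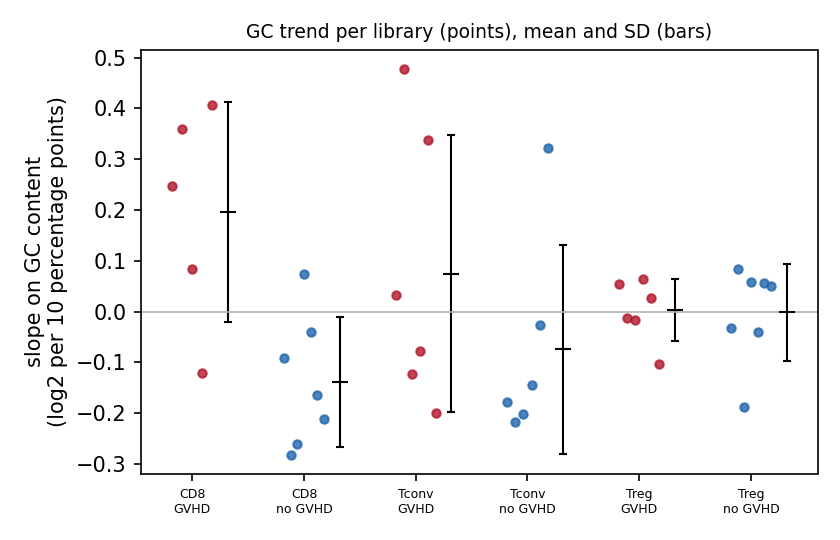
Slope of log2 expression on GC content in each library, relative to the mean of its subset, in log2 per 10 percentage points of GC, with red points for GVHD, blue points for no GVHD, and the mean and SD as bars. The CD8 cohorts lay 0.335 apart, Tconv 0.149 and Treg 0.00397.

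In Tconv, genes of naive and central memory cells were lower and genes of cytotoxic and Th1 effector cells, proliferation and glycolysis stood higher with GVHD, as gene lists called by camera with the preset correlation. With an estimated correlation the calls of the higher lists were lost (adjusted p = 0.397, 0.382, 0.382 and 0.382) and that of the naive list held, though 6 of 100 splits of the libraries, the real one included, called a list in this way. TXK (ENSG00000074966, chromosome 4, 48066393 to 48134256) averaged 9.09 ± 6.06 CPM with GVHD and 53.4 ± 31.6 CPM without (SD, n = 6 and 6). CCR7 (ENSG00000126353, chromosome 17, 40553769 to 40565472), the receptor that guides T cells into lymph nodes, averaged 38.3 ± 12.8 and 140 ± 70.9 CPM. Both were below the no-GVHD median in 6 of 6 GVHD libraries. CXCR3 (ENSG00000186810, chromosome X, 71615916 to 71618517), a chemokine receptor of Th1 cells, averaged 172 ± 18.5 CPM with GVHD and 64.4 ± 41.2 CPM without. TBX21, which encodes the Th1 transcription factor T-bet, averaged 157 ± 101 and 52.9 ± 24.4 CPM, both above the no-GVHD median in 6 of 6.

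Over all 16719 genes tested in Tconv, edgeR's quasi-likelihood test called 0 higher and 0 lower (smallest adjusted p = 0.0682), with 2494 genes at an unadjusted p under 0.05 where chance gives 836. Of GVHD calls in Tconv, DESeq2 made 97 higher and 216 lower. With the trend on GC content and transcript length taken out it made 834, of which 267 were among the 313 before. With sample weights limma-voom called 1 higher (PLEKHF1, named after its values were seen, adjusted p = 0.0457) and 1 lower (TXK, adjusted p = 0.0306). Without a low-count filter edgeR called 25 higher and 74 lower. Named genes among them were TXK, CCR7, MAL, CXCR3, TBX21, FASLG, IFNGR2, TNFSF8, MCF2L, IFI44L, ADGRG1, ZNF683, FGFBP2, VAV3, FOXP3 and IKZF2. Leaving out GVHD replicate 3 gave 17 calls by edgeR, 0 higher and 17 lower, IFNGR2, TNFSF8, MCF2L and TXK among them, and leaving out no-GVHD replicate 4 gave 1, IFNGR2 (adjusted p = 0.0195). Without the 2 libraries with more than 4 percent of counts in mitochondrial genes, a setting chosen after seeing the data, edgeR called 0 genes. The genes closest to the threshold were lower with GVHD. IFNGR2 (ENSG00000159128, chromosome 21, 33402896 to 33479348), the signalling chain of the interferon gamma receptor, had a log2 fold change of -2.62 ± 0.40 SE (2.16 ± 0.900 against 13.4 ± 6.62 CPM). TNFSF8, the CD30 ligand, had -1.37 ± 0.22. MCF2L, a guanine exchange factor, had -3.35 ± 0.55 and TXK -2.55 ± 0.42, all 4 at an adjusted p of 0.0682 by edgeR. On the higher side, FASLG, the ligand of the death receptor Fas, had 2.44 ± 0.55 (5.46 ± 4.28 against 1.003 ± 0.497 CPM, edgeR adjusted p = 0.222). At the same adjusted p stood the ribosome rescue factor gene PELO (1.15 ± 0.26) and PHF13, a chromatin reader (1.08 ± 0.23).

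Of the 15 fixed panel genes, 7 were higher and 3 lower in Tconv with GVHD when adjusted over the list alone, against 0 over all genes tested by edgeR. The higher genes included CXCR3 (log2 fold change 1.42 ± 0.33 SE), TBX21 (1.57 ± 0.40), HLA-DRA (1.19 ± 0.41) and the activation marker CD38 (1.29 ± 0.54), besides IFNG, interferon gamma (1.08 ± 0.46), GZMB (1.73 ± 0.73) and ITGB7. The lower genes were CCR7 (-1.87 ± 0.35), TCF7, a transcription factor of long-lived T cells (-0.82 ± 0.21), and the inhibitory receptor TIGIT (-1.59 ± 0.65). Without GVHD replicate 2 GZMB had 1.145, without GVHD replicate 5 HLA-DRA had 0.73, and without no-GVHD replicate 6 TIGIT had -0.98.

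The naive and central memory list had a median log2 fold change of -0.85 over 17 genes in Tconv, 13 of them below 0. Among the lists its call held with either correlation (camera adjusted p = 1.2e-08 preset, adjusted p = 0.00992 with an estimated correlation). With the trend on GC content and transcript length taken out, the call held at the preset correlation and was lost at an estimated one (adjusted p = 0.107). When adjusted over the list alone 9 genes fell and 0 rose, against 0 over all genes tested by edgeR. Besides TXK, CCR7 and TCF7 these included MAL (-1.73 ± 0.40 SE, 14.2 ± 8.31 against 46.9 ± 21.4 CPM). The mean of the 17 genes on the log2(CPM + 1) scale was 6.14 ± 0.209 with GVHD and 7.14 ± 0.278 without, lower in 6 of 6 (exact permutation test, two-sided, p = 0.00217, the smallest that 924 splits allow, adjusted p = 0.121 over 69 tests). This score test was chosen after seeing the data. Even at its smallest p in Tconv it cannot pass over 69 tests unless other tests have very small p too. In Treg, where p could reach 0.000583, this list had an exact p of 0.00350 (adjusted p = 0.121). Of the 69 scores 0 passed, with 10 at an unadjusted p under 0.05. In Tconv the cytotoxic, Th1 and proliferation scores had an exact p of 0.136, 0.0866 and 0.0563 (adjusted p = 0.337, 0.297 and 0.297). Type I interferon scores had an exact p of 0.274, 0.186 and 0.259 in CD8, Tconv and Treg.

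**Figure D3:**
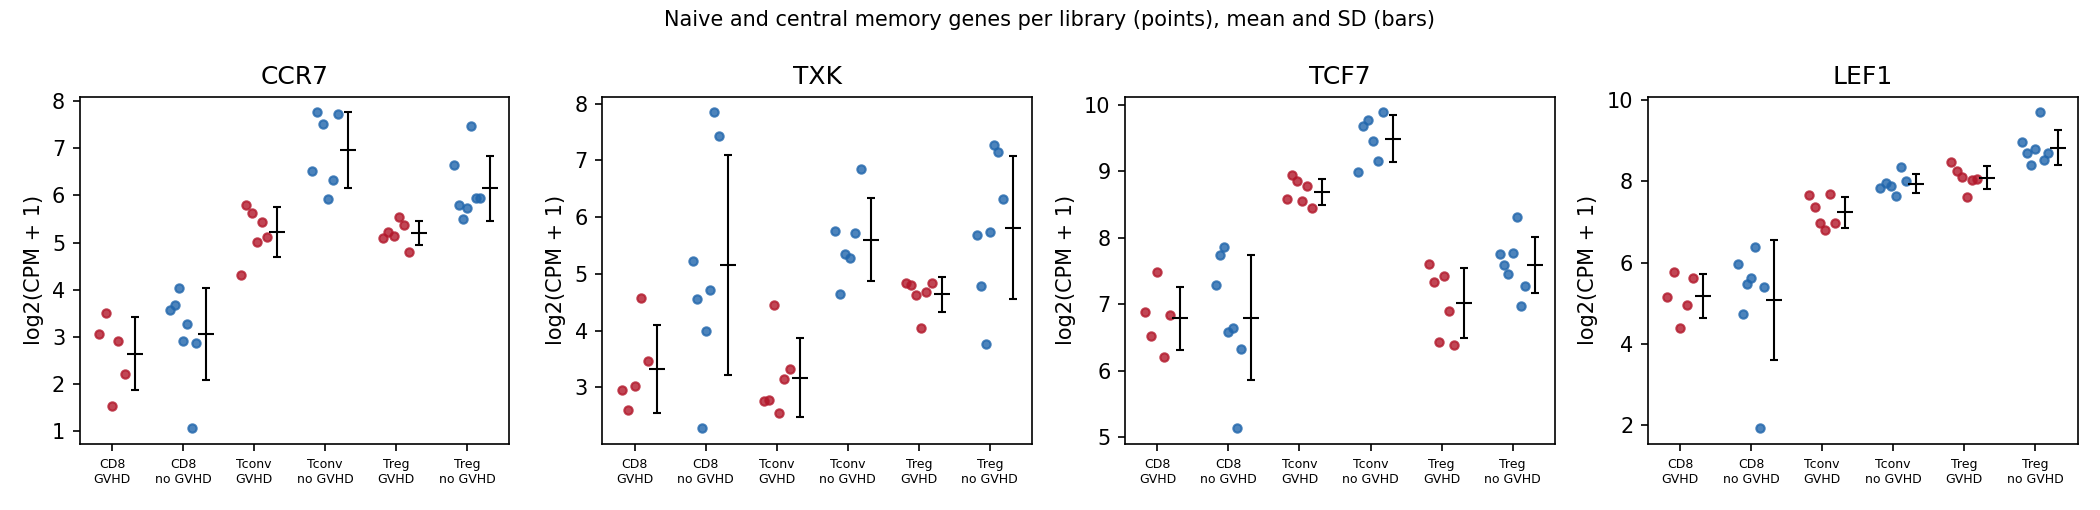
Level of CCR7, TXK, TCF7 and LEF1 in each library as log2(CPM + 1), by subset and cohort, with red points for GVHD, blue points for no GVHD, and the mean and SD as bars. In Tconv the 6 GVHD libraries averaged 38.3 CPM of CCR7 against 140 CPM without GVHD, and in Treg 36.1 against 78.4 CPM; by edgeR with its low-count filter no gene passed over all genes tested.

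Cytotoxic effector genes had a median of 1.58 in Tconv with 18 of 18 above 0 (camera adjusted p = 4.9e-07, and adjusted p = 0.397 with an estimated correlation). When adjusted over the list alone 11 were higher and 0 lower, against 0 over all genes by edgeR: among them were ADGRG1, an adhesion receptor of cytotoxic cells (log2 fold change 3.85 ± 0.96 SE), ZNF683 (3.91 ± 1.17) and FGFBP2 (3.41 ± 1.03). ADGRG1 averaged 81.3 ± 125 CPM with GVHD and 5.63 ± 4.36 CPM without. GVHD replicate 2 held 326 CPM of it, and without that library its log2 fold change was 2.52. With the trend on GC content and transcript length taken out, the cytotoxic median was 1.15, with 4 genes higher over the list alone. Th1 genes had a median of 0.74 (camera adjusted p = 0.00125, and adjusted p = 0.382 with an estimated correlation), with CXCR3 and TBX21 higher and 0 lower over the list alone, against 0 over all genes by edgeR. IL12RB1, an interleukin 12 receptor chain, had 0.83 ± 0.29. Without GVHD replicate 5 the Th1 median was 0.45. With the trend on GC content and transcript length taken out it was 0.57, with 5 genes higher over the list alone. Proliferation genes had a median of 0.93 with 26 of 26 above 0 (camera adjusted p = 3.2e-14, and adjusted p = 0.382 with an estimated correlation), with 0 passing over the list alone or over all genes by edgeR. BIRC5, the mitotic regulator survivin, had 1.44 ± 0.42, the thymidine kinase TK1 1.49 ± 0.48 and the replication clamp PCNA 1.07 ± 0.42.

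Type I interferon response genes in Tconv had a median of -0.83 with 20 of 23 below 0 (camera adjusted p = 0.00125, and adjusted p = 0.541 with an estimated correlation). Of these, 8 were lower and 0 higher when adjusted over the list alone, against 0 over all genes by edgeR. IFI44L had a log2 fold change of -4.01 ± 0.92 SE (5.74 ± 4.94 against 93.0 ± 119 CPM), and the antiviral GTPases MX1 and MX2 had -1.63 ± 0.51 and -1.31 ± 0.37. Without no-GVHD replicate 6 this list had a median of -0.25 and was no longer called (adjusted p = 0.144 by camera), and MX1 had -1.07. Interferon gamma response genes had a median of 0.66 with 16 of 18 above 0 (camera adjusted p = 1.6e-06, and adjusted p = 0.382 with an estimated correlation). In that list 6 genes were higher and 0 lower over the list alone, against 0 over all genes by edgeR, among them PSMB10 (1.02 ± 0.33) and TAP1 (1.002 ± 0.33). With the trend on GC content and transcript length taken out, the interferon gamma median was 0.56 and 0 genes passed over the list alone.

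Metabolic lists were higher in Tconv with GVHD by camera. Glycolysis genes had a median of 0.60 (adjusted p = 1.8e-06, and adjusted p = 0.382 with an estimated correlation). In this list 5 were higher and 0 lower over the list alone, against 0 over all genes by edgeR, including the enzymes GPI (0.85 ± 0.25) and TPI1 (1.12 ± 0.35). Oxidative phosphorylation genes had a median of 0.54 (adjusted p = 2.7e-06, and adjusted p = 0.408 with an estimated correlation) with 0 passing either way. UQCRC1, a complex III subunit, had 0.79 ± 0.27. With the trend on GC content and transcript length taken out, the oxidative phosphorylation median was 0.06 (camera adjusted p = 0.00846). The glycolysis median was then 0.49, with 0 genes passing over the list alone. Cholesterol synthesis genes had a median of 0.21 (adjusted p = 0.0366, and adjusted p = 0.397 with an estimated correlation). Heat shock and unfolded protein genes had a median of 0.33 (adjusted p = 0.0207, and adjusted p = 0.397 with an estimated correlation), with the chaperone HSPA5 at 0.58 ± 0.25. In all, 0 genes of either list passed over the list alone or over all genes by edgeR. The cholesterol call was lost without GVHD replicate 2, 4, 5 or 6 or no-GVHD replicate 4, 5 or 6, with adjusted p from 0.0508 to 0.120 by camera. Without GVHD replicate 5 the median of oxidative phosphorylation was 0.31 and that of heat shock genes 0.21, and HSPA5 had 0.29. The heat shock call was lost without GVHD replicate 4 or 5 or no-GVHD replicate 6, with adjusted p from 0.0508 to 0.137 by camera.

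Lower in Tconv with GVHD were also the regulatory T cell and glucocorticoid response lists. In the first, with a median of -0.36 (camera adjusted p = 0.0200, and adjusted p = 0.397 with an estimated correlation), 4 genes were lower and 1 higher over the list alone, against 0 over all genes by edgeR. They included FOXP3 (1.98 ± 0.573 against 8.96 ± 10.2 CPM), IKZF2 (4.89 ± 3.88 against 25.7 ± 22.7 CPM) and VAV3, a signalling exchange factor (-1.28 ± 0.25). No-GVHD replicate 6 held 29.2 CPM of FOXP3, and without it the log2 fold change of FOXP3 went from -2.18 to -1.31. That call was lost without GVHD replicate 6 or no-GVHD replicate 5 or 6, with adjusted p from 0.0517 to 0.120 by camera. Its median was -0.10 without no-GVHD replicate 6, -0.20 without GVHD replicate 2 and -0.71 without GVHD replicate 3. In the glucocorticoid list, with a median of -0.23 (camera adjusted p = 0.0273, and adjusted p = 0.404 with an estimated correlation), 1 gene was lower and 0 higher over the list alone, against 0 over all genes by edgeR. It was CD163, a scavenger receptor of monocytes and macrophages (0.463 ± 0.424 against 3.16 ± 2.49 CPM), while BIRC3, an inhibitor of apoptosis, had -1.16 ± 0.44. The glucocorticoid call was lost without GVHD replicate 1, 3 or 6 or no-GVHD replicate 5, with adjusted p from 0.0558 to 0.186 by camera. Its median was -0.09 without no-GVHD replicate 5, -0.41 without GVHD replicate 2 or no-GVHD replicate 2, -0.46 without GVHD replicate 5 and -0.38 without no-GVHD replicate 4. Without the 2 Tconv libraries of high mitochondrial share, camera called 10 of the lists in place of 14. The mitochondrial share in Tconv averaged 2.48 ± 2.72 percent with GVHD and 1.47 ± 1.59 percent without, above the no-GVHD median in 6 of 6 (exact p = 0.457, adjusted p = 0.822 over 45 tests). The slope of expression on transcript length averaged -0.0895 ± 0.190 log2 per doubling in Tconv with GVHD and 0.0896 ± 0.0963 without (exact permutation test, two-sided, p = 0.0649, adjusted p = 0.128 over 6 tests, above the no-GVHD median in 0 of 6).

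Monocyte markers in Tconv had a median of -1.84 with 10 of 10 below 0 (camera adjusted p = 3.5e-08, and adjusted p = 0.382 with an estimated correlation), and 9 were lower and 0 higher over the list alone, against 0 over all genes by edgeR. CD14, a monocyte coreceptor for lipopolysaccharide, averaged 2.53 ± 2.21 CPM with GVHD and 11.7 ± 10.1 CPM without. S100A9, a calcium-binding protein of myeloid cells, averaged 6.48 ± 2.86 and 19.7 ± 12.8 CPM, and FCN1, a secreted monocyte lectin, 5.52 ± 4.67 and 23.03 ± 17.4 CPM. CD8 lineage markers had a median of -0.82 (camera adjusted p = 0.0200, and adjusted p = 0.382 with an estimated correlation). In it 1 was lower and 0 higher over the list alone, against 0 over all genes by edgeR. This was CRTAM, an adhesion gene of activated T cells, at 0.143 ± 0.121 against 0.639 ± 0.351 CPM. The CD8 lineage call was lost without GVHD replicate 3 (adjusted p = 0.121 by camera, median -0.53) or no-GVHD replicate 5 (adjusted p = 0.0935).

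In Treg, proliferation genes were higher and naive and central memory genes lower with GVHD as lists, alongside higher levels of GZMA and IFNG that did not pass over all genes by edgeR within the subset and did by DESeq2. The list calls were made by camera with the preset correlation and were lost with an estimated one (adjusted p = 0.300 and 0.104). GZMA (ENSG00000145649, chromosome 5, 55102648 to 55110252), the cytotoxic protease granzyme A, averaged 52.5 ± 18.2 CPM with GVHD and 12.2 ± 6.22 CPM without (SD, n = 6 and 7). It had a log2 fold change of 2.11 ± 0.35 SE (edgeR adjusted p = 0.221, and 0.00267 without a low-count filter). IFNG (ENSG00000111537, chromosome 12, 68154768 to 68159747) averaged 14.4 ± 11.7 and 1.85 ± 1.38 CPM (2.95 ± 0.63, edgeR adjusted p = 0.850). In one model over all 6 groups edgeR called GZMA in Treg (adjusted p = 0.0360) and IFNG in Treg (adjusted p = 0.0306). Both lay above the no-GVHD median in 6 of 6 GVHD libraries.

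Over all 16565 genes tested in Treg, edgeR's quasi-likelihood test called 0 higher and 0 lower (smallest adjusted p = 0.221), with 951 genes at an unadjusted p under 0.05 where chance gives 828. DESeq2 called 3 higher and 1 lower, limma-voom with sample weights called 0, and edgeR in one model over all 6 groups called 6 higher and 3 lower. The DESeq2 calls were GZMA (adjusted p = 2.3e-05), IFNG (adjusted p = 0.00447) and SYTL2 (adjusted p = 0.0187) higher and PTGDS (adjusted p = 0.0122) lower. Without the library of 3.402 M counts, a setting chosen after seeing the data, edgeR called 0 genes and camera 12 lists in place of 13. Other genes of small p, named as not passing, were SYTL2, a vesicle transport gene (log2 fold change 1.501 ± 0.32 SE), ERCC6L, a mitotic helicase (1.502 ± 0.39), and MT-CO3, a gene of the mitochondrial genome (0.57 ± 0.14). On the lower side stood the prostaglandin D2 synthase PTGDS (-1.94 ± 0.43, 3.30 ± 1.69 against 12.6 ± 5.83 CPM), KIAA1324L (-1.33 ± 0.35), and TRIM22, an interferon-induced antiviral gene (-0.63 ± 0.17). Of the 15 panel genes 1 was higher (IFNG) and 1 lower (CCR7, 36.1 ± 6.49 against 78.4 ± 46.9 CPM) over the list alone, against 0 over all genes by edgeR. CXCR3 had 1.04 ± 0.36, TBX21 0.77 ± 0.34, TCF7 -0.56 ± 0.24 and the proliferation marker MKI67 0.78 ± 0.31.

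Proliferation genes in Treg had a median log2 fold change of 0.85 with 26 of 26 above 0 (camera adjusted p = 1.1e-26, and adjusted p = 0.300 with an estimated correlation). When adjusted over the list alone 21 were higher and 0 lower, against 0 over all genes by edgeR. The replication helicase gene MCM4 averaged 276 ± 101 CPM with GVHD and 132 ± 61.4 CPM without, MCM2 of the same helicase 236 ± 74.4 and 123 ± 62.8 CPM, and BIRC5 83.9 ± 39.9 and 33.8 ± 22.1 CPM. Naive and central memory genes had a median of -0.40 with 14 of 16 below 0 (camera adjusted p = 4.7e-07, and adjusted p = 0.104 with an estimated correlation). Of them 5 were lower and 0 higher over the list alone, against 0 over all genes by edgeR. LEF1, a transcription factor of naive T cells, averaged 276 ± 52.9 CPM with GVHD and 475 ± 167 CPM without, TXK 24.4 ± 4.67 and 73.9 ± 54.9 CPM, and MAL 43.6 ± 14.4 and 77.7 ± 27.7 CPM. Cytotoxic effector genes had a median of 0.67 (camera adjusted p = 1.6e-05, and adjusted p = 0.335 with an estimated correlation). Over the list alone 3 were higher and 0 lower, against 0 over all genes by edgeR. They were GZMA, the granzyme GZMK (24.6 ± 17.9 against 4.04 ± 3.46 CPM) and ZNF683 (2.84 ± 2.26 against 0.257 ± 0.339 CPM). FGFBP2 averaged 4.74 ± 3.74 and 1.07 ± 0.921 CPM and did not pass. Th1 genes had a median of 0.43 (camera adjusted p = 0.00396, and adjusted p = 0.335 with an estimated correlation), with IFNG higher and 0 lower over the list alone, against 0 over all genes by edgeR. Without GVHD replicate 1 or 2 the Th1 median was 0.15 or 0.24. Without no-GVHD replicate 7 it was 0.78 and that of the cytotoxic list 1.04. Without no-GVHD replicate 5 the naive and central memory median was -0.26.

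Type I interferon response genes in Treg had a median of -0.92 with 23 of 23 below 0 (camera adjusted p = 4.6e-07, and adjusted p = 0.404 with an estimated correlation), and 0 passed over the list alone or over all genes by edgeR. The antiviral gene RSAD2 averaged 2.71 ± 1.88 CPM with GVHD and 27.2 ± 42.1 CPM without, IFI44L 11.5 ± 12.97 and 104 ± 157 CPM, and MX1 176 ± 64.7 and 400 ± 296 CPM. Glycolysis genes had a median of 0.29 (camera adjusted p = 3.1e-05, and adjusted p = 0.335 with an estimated correlation), with GPI at 0.55 ± 0.16 and GAPDH at 0.62 ± 0.22. Oxidative phosphorylation genes had a median of 0.29 (camera adjusted p = 2.6e-05, and adjusted p = 0.404 with an estimated correlation), with the ATP synthase subunit gene ATP5F1A at 0.34 ± 0.16. Heat shock and unfolded protein genes had a median of 0.30 (camera adjusted p = 0.00318, and adjusted p = 0.335 with an estimated correlation), with the mitochondrial chaperone HSPD1 at 0.57 ± 0.22. In the last 3 lists 0 genes passed over the list alone or over all genes by edgeR. The type I interferon median was -0.57 and RSAD2 had -2.135 without no-GVHD replicate 7, and the heat shock median 0.17 without GVHD replicate 5. With the trend on GC content and transcript length taken out, the type I interferon median was -1.02. The glycolysis, oxidative phosphorylation and heat shock medians were then 0.28, 0.19 and 0.11.

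Weaker list calls in Treg were lost without single libraries, and 0 of their genes passed over the list alone or over all genes by edgeR. Interferon gamma response genes had a median of 0.18 (camera adjusted p = 0.0428, and adjusted p = 0.532 with an estimated correlation), led by the proteasome genes PSMB8 (0.33 ± 0.14) and PSME2 (0.57 ± 0.27). Notch pathway genes had a median of -0.26 (camera adjusted p = 0.0442, and adjusted p = 0.335 with an estimated correlation), with the coactivator MAML2 at -0.60 ± 0.24 and the protease ADAM10 at -0.49 ± 0.23. Genes induced by p53 had a median of -0.16 (camera adjusted p = 0.0462, and adjusted p = 0.335 with an estimated correlation), with the cell cycle inhibitor CDKN1A at -0.85 ± 0.41. By camera, leaving out GVHD replicate 1 or 2 or no-GVHD replicate 2, 3, 4 or 5 gave the interferon gamma list an adjusted p of 0.0617 to 0.397. Leaving out GVHD replicate 1, 2 or 5 or no-GVHD replicate 1, 2, 4, 6 or 7 gave the Notch list an adjusted p of 0.0543 to 0.123. Leaving out GVHD replicate 1, 2, 3 or 6 or no-GVHD replicate 3, 4, 5, 6 or 7 gave the p53 list an adjusted p of 0.0505 to 0.209. The interferon gamma median was 0.08 without GVHD replicate 1, 0.11 without GVHD replicate 2, 0.29 without GVHD replicate 4 and 0.31 without no-GVHD replicate 6. The Notch median was -0.17 and CDKN1A had -0.38 without no-GVHD replicate 1. Without no-GVHD replicate 5 MAML2 had -0.39, and the p53 median was -0.07 without no-GVHD replicate 3.

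Markers of monocytes and platelets stood lower in Treg with GVHD as lists. Monocyte markers had a median of -0.98 with 11 of 11 below 0 (camera adjusted p = 0.000493, and adjusted p = 0.430 with an estimated correlation), with S100A9 at 65.3 ± 57.4 CPM with GVHD and 132 ± 117 CPM without. Platelet markers had a median of -1.61 with 4 of 4 below 0 (camera adjusted p = 0.0428, and adjusted p = 0.415 with an estimated correlation), with the platelet chemokine PF4 at 0.438 ± 0.613 and 3.06 ± 4.24 CPM. In all, 0 genes of either list passed over the list alone or over all genes by edgeR. The platelet call was lost without GVHD replicate 1, 2 or 4 or no-GVHD replicate 1, 4 or 5, with adjusted p from 0.0517 to 0.184 by camera. Its median was -1.07 without no-GVHD replicate 5, and the log2 fold change of PF4 went from -2.82 to -1.83. Without no-GVHD replicate 1 the monocyte median was -0.18 (adjusted p = 0.0309 by camera), and S100A9 went from -1.02 to -0.64. The mitochondrial share of counts averaged 1.04 ± 0.350 percent with GVHD and 0.709 ± 0.124 percent without, above the no-GVHD median in 6 of 6 (exact permutation test, two-sided, p = 0.00291, adjusted p = 0.131 over 45 tests). The slope of expression on transcript length averaged -0.0409 ± 0.0799 log2 per doubling with GVHD and 0.0351 ± 0.0661 without (exact p = 0.0851, adjusted p = 0.128 over 6 tests).

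**Figure D4:**
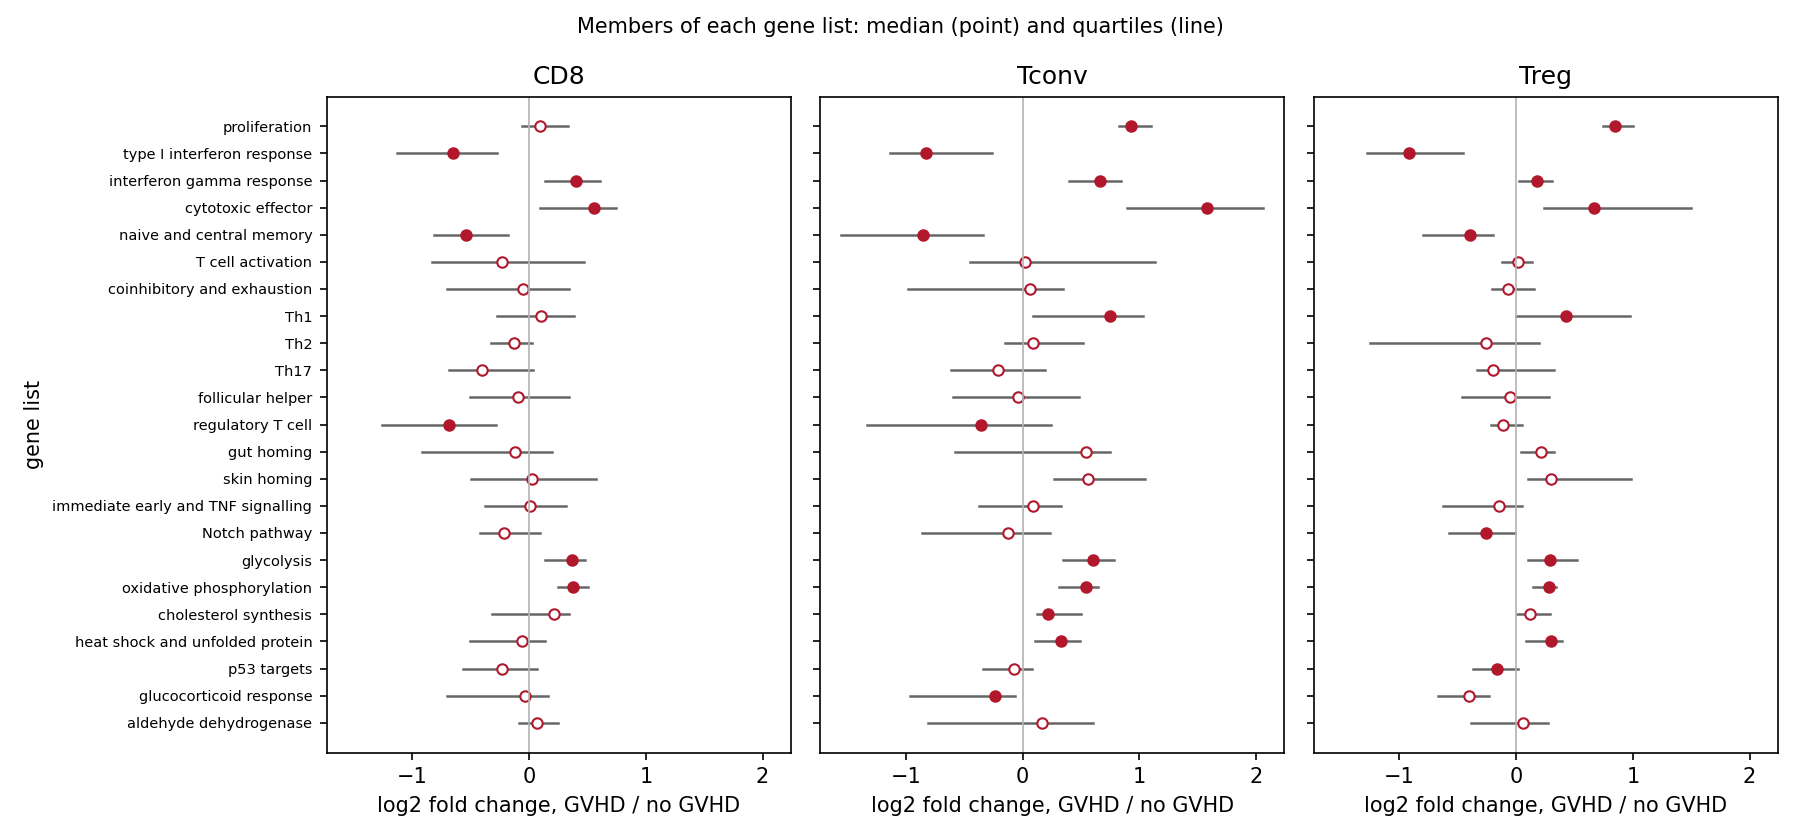
Median log2 fold change (point) and quartiles (line) of the members of each fixed list between GVHD and no GVHD, in CD8, Tconv and Treg, with filled points for lists called by camera with the preset correlation. Naive and central memory genes lay at -0.54, -0.85 and -0.40 and type I interferon response genes at -0.65, -0.83 and -0.92; with an estimated correlation 1 of the calls remained, that of the naive and central memory list in Tconv.

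Across the 3 subsets 9 lists were called in none of them by camera in the main fits (27 tests, adjusted p from 0.123 to 0.980). In CD8, Tconv and Treg in turn, the median log2 fold changes of T cell activation genes were -0.23, 0.02 and 0.02, and those of coinhibitory and exhaustion genes -0.05, 0.07 and -0.07. Th2 genes had -0.13, 0.09 and -0.26, Th17 genes -0.40, -0.22 and -0.20 and follicular helper genes -0.09, -0.04 and -0.05. Gut homing genes had -0.12, 0.54 and 0.22 and skin homing genes 0.02, 0.56 and 0.30. Immediate early and TNF signalling genes had 0.01, 0.09 and -0.15, and aldehyde dehydrogenases, the enzymes that break down cyclophosphamide metabolites, had 0.07, 0.17 and 0.06. Over the list alone, 1 gut homing gene was higher and 3 lower in CD8, and 2 T cell activation genes were higher there. In Tconv 3 gut homing genes were higher and 2 follicular helper genes lower. The coinhibitory, Th2, immediate early and aldehyde dehydrogenase lists each had 1 lower in Tconv. Over all genes 0 of these passed by edgeR. Median, mean and test differed in sign in 11 of these 27 tests and in 0 of the 34 called ones. Proliferation genes in CD8 had a median of 0.10 and were not called (camera adjusted p = 0.0678), though they were with the trend on GC content and transcript length taken out (adjusted p = 7.3e-05, and adjusted p = 0.778 with an estimated correlation). In CD8 that setting also called T cell activation genes as higher (camera adjusted p = 0.0319, median -0.0002). It called heat shock and unfolded protein genes as lower (camera adjusted p = 0.0354, median -0.31). With an estimated correlation both had an adjusted p of 0.423.

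Whether the GVHD effect differed between subsets was tested in one model over all 6 groups. Of 20335 genes edgeR called 0 for CD8 against Tconv, 0 for CD8 against Treg and 0 for Treg against Tconv, with 635, 1334 and 578 genes at an unadjusted p under 0.05 where chance gives 1017. DESeq2 called 1, 7 and 2 genes and limma-voom 0, 0 and 0. Named after their values were seen, the DESeq2 calls for Treg against Tconv were the noncoding gene LINC00689 (log2 difference -20.16, adjusted p = 5.2e-06) and the protocadherin PCDHGB3 (-6.75, adjusted p = 0.0281). That for CD8 against Tconv was the noncoding RNA gene ENSG00000276312 (-33.57, adjusted p = 0.00214). These sizes rest on groups at or near 0 counts. LINC00689 was counted in 0 and PCDHGB3 in 1 of 6 Treg libraries with GVHD, and ENSG00000276312 in 0 of 6 Tconv libraries without. Among the named genes, none of which passed here, IFNG had a log2 difference of -3.38 ± 0.79 SE for CD8 against Treg (edgeR adjusted p = 0.401). The cell cycle kinase CDK6 (-1.996 ± 0.44) and the endoplasmic reticulum chaperone HSP90B1 (-1.26 ± 0.30) had the same adjusted p, and FOXP3 had 2.03 ± 0.55 for Treg against Tconv (edgeR adjusted p = 0.893). An effect seen in one subset was therefore not shown to be absent from another.

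Shared genes were counted between subsets in the same direction. At an adjusted p under 0.05 by edgeR 0 genes were shared in any pair. At an unadjusted p under 0.01, Tconv and Treg shared 19 higher genes where independent lists give 1.52 and 31 lower genes where they give 1.30. CD8 and Tconv shared 11 higher genes against 1.06 and 11 lower genes against 3.49, and CD8 and Treg shared 1 against 0.483 and 6 against 0.639. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.518 for Tconv and Treg, 0.456 for CD8 and Tconv and 0.208 for CD8 and Treg. In CD8, Tconv and Treg in turn, the fold changes had a Spearman rho of 0.729, 0.314 and 0.00773 with GC content. With transcript length rho was -0.380, -0.337 and -0.205. Whether such shared trends raise the overlaps and correlations was not tested. The labels do not say whether libraries of different subsets came from the same patients, so part of this sharing could not be assigned to the cohort.

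Scores of 11 marker lists and 4 measures of library quality were compared between cohorts in each subset by exact permutation tests, two-sided, and 0 of 45 passed an adjusted p of 0.05, with 5 at an unadjusted p under 0.05. The monocyte score was lower with GVHD by 1.33 in Tconv (exact p = 0.0303, adjusted p = 0.341, 6 of 6 below the no-GVHD median), and the differences were -0.41 in CD8 and -0.96 in Treg on the log2(CPM + 1) scale. The neutrophil and progenitor score was 0.234 ± 0.0656 with GVHD and 0.510 ± 0.211 without in Tconv (exact p = 0.0108, adjusted p = 0.244). The CD8 lineage score in Tconv was 0.622 ± 0.406 and 1.11 ± 0.303 (exact p = 0.0390, adjusted p = 0.351). The 50 most abundant genes took 17.1 ± 1.93 percent of counts in CD8 with GVHD and 14.7 ± 1.16 percent without (exact p = 0.0240, adjusted p = 0.341). In CD8, Tconv and Treg in turn, the differences were 0.09, -0.175 and -0.12 for B cells, -0.02, 0.01 and -0.01 for plasma cells, and 0.11, 0.00 and -0.06 for NK cells. They were -0.18, -0.24 and 0.47 for gamma delta T cells, -0.29, -0.18 and 0.07 for erythroid cells, -0.01, -0.07 and -0.11 for dendritic cells, -0.13, -0.34 and -0.53 for platelets and 0.09, 0.35 and 0.32 for the CD4 lineage.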

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

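The rule that picked out the values below was fixed in advance; of the tests in this part, the simulation of how often the rule picks out a group by chance was chosen only after the result was seen. In each of 250 groups of 5 to 7 libraries, a library was picked out when its distance to the nearest other was a large share of the range of its group. For independent, normally distributed values chance alone gives about 5.10 percent of groups, or 12.75 of the 250, and 34 were picked out, in 17 libraries. Of these, 27 were CPM values of genes, which need be neither normally distributed nor independent of each other. The excess over 12.75 therefore does not show that these libraries deviate. A single value below is therefore not evidence on its own.

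Library measures were far from their group in 5 libraries. Tconv GVHD replicate 5 had the lowest total, 12.05 M counts (M for mega) against 27.9 to 35.2, the highest mitochondrial share, 8.01 percent against 1.09 to 1.92 percent, and 20569 genes detected against 23765 to 25063. Treg no-GVHD replicate 6 had 3.402 M counts against 16.7 to 23.7. The mitochondrial share was 4.68 percent in Tconv no-GVHD replicate 5 against 0.292 to 1.05 percent, and 1.74 percent in Treg GVHD replicate 1 against 0.811 to 1.03 percent. The GC slope was 0.32 log2 per 10 percentage points in Tconv no-GVHD replicate 6 and lay from -0.22 to -0.03 in the others.

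In CD8, TXK stood at 22.9 CPM in GVHD replicate 4 against 5.06 to 10.1 CPM, and MAL at 160 CPM in no-GVHD replicate 6 against 1.14 to 18.01 CPM. The interferon response gene IFI44L stood at 5.81 CPM in GVHD replicate 3 against 0.731 to 1.68 CPM and at 188 CPM in no-GVHD replicate 7 against 0.457 to 30.1 CPM. IFIT1 stood at 48.6 CPM in no-GVHD replicate 7 against 0.740 to 18.3 CPM. In Tconv, TXK stood at 21.04 CPM in GVHD replicate 3 against 4.83 to 9.08 CPM and at 114 CPM in no-GVHD replicate 6 against 23.95 to 52.97 CPM. The cytotoxic gene ADGRG1 stood at 326 CPM in GVHD replicate 2 against 3.27 to 95.3 CPM and at 13.9 CPM in no-GVHD replicate 5 against 1.41 to 5.93 CPM, and FGFBP2 at 40.9 CPM in the latter against 3.11 to 10.5 CPM. FOXP3 stood at 29.2 CPM in no-GVHD replicate 6 against 2.52 to 8.70 CPM. GVHD replicate 5 held 649 CPM of GPI against 275.9 to 410.2 CPM, 612 CPM of TPI1 against 187 to 341 CPM and 933 CPM of HSPA5 against 363 to 484 CPM.

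In Treg without GVHD, replicate 5 held 835 CPM of LEF1 against 337 to 498 CPM, 177 CPM of CCR7 against 44.4 to 99.5 CPM and 12.2 CPM of PF4 against 0 to 2.94 CPM. Replicate 4 held 262 CPM of MCM4 against 80.5 to 137 CPM, 79.95 CPM of BIRC5 against 11.6 to 35.04 CPM and 247 CPM of MCM2 against 68.1 to 144 CPM. It held ATP5F1A at 450.1 CPM against 273.8 to 324.4 CPM and HSPD1 at 179.6 CPM against 73.2 to 104.7 CPM. Replicate 7 held 118 CPM of RSAD2 against 0 to 38.1 CPM, and replicate 1 held 104 CPM of CDKN1A against 11.7 to 42.3 CPM. With GVHD, TXK was at 15.5 CPM in replicate 4, the lowest, against 23.7 to 27.8 CPM, CDKN1A at 44.3 CPM in replicate 4 against 13.4 to 20.3 CPM and PF4 at 1.63 CPM in replicate 5 against 0 to 0.491 CPM.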

How the results depend on the processing

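The tests without the trend on GC content and transcript length, without the libraries of high mitochondrial share or low depth, and of process list scores were chosen only after the result was seen. Among the genes named, 2042 values under planned settings kept side and direction and 79 came past the threshold. Under added settings 377 kept them, 32 came past and 1 reversed. GZMB in CD8 went to -0.054 with the trend removed and limma-voom (adjusted p = 0.937). Of values of lists, 426 planned and 51 added stayed called, and 131 planned and 44 added were no longer called; 117 monocyte score values stayed the same.

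Counts of GVHD calls in CD8 were 52 by DESeq2, 536 by limma-voom and 42 by DESeq2 with the trend removed. In Tconv they were 99 with no filter, 313 by DESeq2, 2 by limma-voom and 834 by DESeq2 with the trend removed. In Treg they were 9 in 1 model over all 6 groups, 1 with no filter (GZMA), 4 by DESeq2 and 4 by DESeq2 with the trend removed. By edgeR, RLE factors, the stricter filter, robust dispersion, the trend removed and the fits without doubtful libraries gave 0 in each subset they were run on. Leaving out 1 library gave 0 to 0 calls in CD8, 0 to 17 in Tconv and 0 to 0 in Treg; in Tconv 17 came without GVHD replicate 3 and 1 without no-GVHD replicate 4. For differences between subsets DESeq2 called 1, 7 and 2, and leaving out 1 library gave 0 to 0 by edgeR. At an unadjusted p under 0.01 the overlaps were 11 and 11 for CD8 and Tconv, 1 and 6 for CD8 and Treg and 19 and 31 for Tconv and Treg.

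Subset calls ranged without 1 library from 1920 to 2490, 5917 to 6712 and 2589 to 3713, and for subset calls CD8 versus Tconv limma-voom gave 5845. Lists called in CD8, Tconv and Treg numbered 0, 1 and 0 with an estimated correlation, 0, 1 and 0 by fry (a test against no change, not against other genes), and 0, 0 and 0 with an estimated correlation after removal of the trend. Without 1 library they ranged from 4 to 10, 10 to 14 and 9 to 14, with 4 in CD8 without GVHD replicate 4. In 1 model over all 6 groups the Tconv glucocorticoid list had an adjusted p of 0.0587 by camera, and in Treg the interferon gamma, Notch and p53 lists had 0.139, 0.153 and 0.123. With the trend removed the calls of the Tconv regulatory T cell list (adjusted p = 0.0944) and heat shock list (adjusted p = 0.0578) and of the Treg Notch (adjusted p = 0.181) and p53 lists (adjusted p = 0.0510) ended. Without the 2 Tconv libraries of high mitochondrial share the calls of the regulatory T cell (adjusted p = 0.0974), cholesterol (adjusted p = 0.199), heat shock (adjusted p = 0.0973) and CD8 lineage lists (adjusted p = 0.0528) ended, and without the shallow Treg library those of the Notch (adjusted p = 0.0717) and p53 lists (adjusted p = 0.0990). For these changes the cause was not tested. No marker score passed with a pseudocount of 0.1 or 5 CPM or without 1 library (0 to 0). No paired analysis was possible because replicate numbers follow the order of deposition and the labels tie no library of one group to one of another. Low depth limits genes near 1 CPM in Treg no-GVHD replicate 6, with 3.402 M counts (M for mega).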

Other observations

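The tests of the trend on GC content and transcript length and of the splits by lists called with an estimated correlation were chosen only after the result was seen, and the choice of the 3 patterns weighed here was made from the data. Other splits of the libraries into groups of the same sizes, 100 drawn with the real one included, were refitted for each comparison. For subset comparisons chance can be excluded: 1 of 100 splits, the real one, gave as many calls in each, with 2308, 6485 and 3205 real calls and at most 243, 73 and 22 in other splits. For GVHD calls the real count of 0 excludes nothing (100 of 100 splits in each subset), and other splits gave a median of 0 and up to 4198 genes in CD8, 170 in Tconv and 136 in Treg. Only 2, 4 and 2 of the other splits called any gene. The 1 split of CD8 with 4198 genes points to a structure of these libraries other than the cohort, by edgeR in that split alone. Genes at an unadjusted p under 0.05 were as many in 22 of 100 splits in CD8 (real 1457, highest other 6664), 7 in Tconv (2494 and 3826) and 19 in Treg (951 and 3069), so chance could not be excluded. For differences between subsets 100 of 100 splits gave as many, with 0 real calls and, in other splits, a median of 0 and up to 2594, 2190 and 6. For the number of lists called by camera with the preset correlation, chance could not be excluded in CD8 (57 of 100 splits, real 7, highest other 13). In Tconv (4 of 100, real 14, highest other 15) and Treg (3 of 100, real 13, highest other 15) it was excluded for that number alone, narrowly and with no allowance for how many results were split. Other splits had a median of 7 called lists in each of the 3 subsets, so a call of a single list there is weak evidence by itself.

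A first pattern was the 536 limma-voom calls in CD8, whose higher genes had a median GC content of 58.3 percent and lower genes 38.5 percent, against 48.4 percent over all genes. Taking the trend on GC content and transcript length out left 0 calls, with the median absolute log2 fold change of those genes going from 0.83 to 0.35 (interquartile ranges 0.33 and 0.35) and 509 of 536 keeping their sign. The calls ended because the effects shrank. Chance could not be excluded either (15 of 100 splits gave as many, highest other 5542, which points again to a structure of the libraries). A trend that differs between libraries is therefore a candidate cause of these calls. A difference due to GVHD that follows GC content remains open and was not tested.

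A second pattern was the lower naive and central memory list in Tconv, with CCR7, TXK and TCF7. The trend on GC content and transcript length is argued against as the whole cause, since the list median was -0.87 once it was removed and -0.85 before, though with an estimated correlation the adjusted p by camera then was 0.107. A single library is argued against as well, since without any 1 of the 12 the median nearest 0 was -0.74 with a highest adjusted p of 1.1e-06 by camera. Its median was as large in 1 of 100 splits (highest other size 0.690). But the list was picked from the data, and 6 of 100 splits called as many lists with an estimated correlation (real 1, highest other 2), so chance could not be excluded. The score test, with an adjusted p of 0.121 over 69 exact permutation tests, cannot decide this. Its p was the smallest that 924 splits allow, which does not pass over 69 tests unless other tests have very small p too. The share of naive and central memory cells, the composition of the sort and differences between patients stay open and were not tested.

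Another pattern was the lower level of monocyte markers in Tconv with GVHD. On total counts, without TMM scaling, LYZ, which encodes lysozyme, averaged 17.9 ± 12.7 CPM with GVHD and 74.6 ± 68.5 CPM without (n = 6 and 6). The proteoglycan gene VCAN averaged 16.7 ± 13.6 and 61.7 ± 56.8 CPM on the same scale. Of these markers, 9 varied together within groups with a mean pairwise correlation of 0.878, against a median of 0.0663 and a 95th percentile of 0.268 in 10000 random lists of like expression. Monocyte RNA in the sorted cells is therefore a candidate source, and Treg libraries held more (LYZ 231 ± 222 and 456 ± 565 CPM on total counts). Whether its amount differs because of GVHD or because of the sort was not tested.

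The DESeq2 calls in Tconv were as many in 7 of 100 splits (real 313, highest other 1490), so chance could not be excluded for them.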
